A study of Mus musculus with 2 samples.

How the data were processed

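DNase-seq of lung tissue from adult male B6CASTF1/J mice was analysed in 2 samples of 1 group, replicates 1 and 2 as the labels number them. Per the labels the assembly is mm10, which is GRCm38, and both libraries come from the same consortium laboratory. For each sample the deposited files were 2 peak lists, a list of footprints and a list of base stretches with the false discovery rate of their cut rate. The aligner, peak caller, footprint caller and thresholds are not given in the sources used here.

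The authors' peak lists carry a signal value per peak. The deposited signal values were whole multiples of 1 step per library within a tolerance of 0.1 for 100% of peaks, so they are whole numbers times a constant. Dividing by the step gave these numbers, which are read here as counts of cuts in the peak. That 1 step is 1 cut was not tested. What the constant stands for is not stated. The deposited footprint lists carry the same p-value-like entry, 0.01, for each footprint, read as the false discovery rate at which the list was made. The deposited lists of base stretches carry a false discovery rate of the cut rate, treated as a p-value unit, with 0.0499 and 0.0500 as the highest in replicates 1 and 2. They covered 41.4 Mb in replicate 1 and 46.7 Mb in replicate 2 at 0.05, and 26.7 and 29.1 Mb at 0.001. The replicates shared 62.2% of the bases covered by either at 0.05 and 64.9% at 0.001.

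The list with the smaller median width was to be the main one. The median was 200 bp for each list, and the tie was broken by the smaller mean width, before any comparison was made, which selected the longer list in both replicates. The longer list's peaks each touch a base with a rate of 0.05 or less, while 67.0% of them in replicate 1 and 65.6% in replicate 2 touch one of 0.001 or less. All peaks of the shorter list do. Of the shorter list's peaks 98.9% and 98.8% overlap the longer list, so the shorter list served as a stricter alternative. Chromosomes 1 to 19, X and Y were used.

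Genes, transcripts and exons came from GENCODE M21 and sequence from GRCm38.p6, with 21938 protein-coding genes and 132629 transcript starts. Peaks were shared when they overlapped by at least 1 bp, and values were compared over pairs that were each other's best overlap. Chance overlap and location came from 100 random placements within the ungapped part of each chromosome. The test of each pair against counting error was a 2-sided exact binomial test conditional on the sum of cuts, around the median ratio. Locations were assigned by peak midpoint, with promoters first.

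Gene lists, motif sequences, tests and 26 alternatives were fixed before the data were examined. The 33 lists held 408 genes: cell types of the lung, blood cells, cell types foreign to lung, and regulators. A promoter was open when a shared peak overlapped 1000 bp on either side of any transcript start of the gene. Such a peak can lie at the start of a neighbouring gene. Promoter values are sums over all peaks of each replicate's own list that overlap these windows, shared or not. They can exceed the value of any single site. They are given as mean and SD over the replicates, without scaling between the libraries. The SD therefore includes the overall difference between the libraries, a median log2 ratio of replicate 2 to replicate 1 of -0.33 at promoters. Lists were tested against all other protein-coding genes by 2-sided Fisher's exact test. Distal sites were shared peaks outside promoters with their midpoint in the gene body or 10000 bp on either side. The list mean was placed among 10000 random lists matched on gene length in 20 bins, with a 2-sided permutation p. For the ratio between replicates, peak values were summed over the same window, and the list median of log2(replicate 2/replicate 1), minus the median of the 17859 protein-coding genes with a value in both, was placed among 10000 random lists matched on mean value in 20 bins. These sums run over each replicate's own peaks, so a peak missing from 1 list adds nothing there. They include promoter peaks of neighbouring genes in the window, and genes close together share part of their windows. Peak numbers, lengths and mean values per list were summed over genes. A peak in the windows of several members counts once for each. Benjamini-Hochberg adjustment was made over lists or motifs with a threshold of 0.05.

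Motifs were 24 fixed consensus sequences searched on both strands in footprints inside peaks, with 5 bp added on each side, and in a window of the same width at a random place in the same peak off all footprints. Such a window was found for 98.2% and 98.4% of footprints inside peaks. P-values under 1e-300 were set to it. Motifs with 9 or fewer window matches were given as ratios of counts with exact 95% intervals, and 0 matches as 3 counts.

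The genes named are, per list, up to 4 members with the highest mean promoter value and up to 2, in alphabetical order, without a promoter peak in either replicate, 171 genes in all, of which the text gives examples. Some members under this rule are not reported here. The text also names the 10 shared peaks with the highest mean value, the 5 with the largest ratio in each direction among shared peaks above the median value, and motifs past the threshold in both replicates. Cd79b, Msln and similar members are named under this rule with their ratio over the gene body and, for some, at the promoter. Motifs that passed in 1 replicate, in opposite directions or under an alternative are named in addition, after their values were seen.

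After the data were seen, 3 alternatives were added: the ratio between replicates without mostly repeat-masked peaks (over 80% soft-masked bases) and without X and Y, the same ratio over shared peaks only, and sharing without mostly repeat-masked peaks. The tests of explanations, 5 further gene lists with no member in the first 33, and the motif content of distal sites were also chosen after the data were seen. In these tests the ratio is the median over a gene's shared peaks, centred on all shared peaks, before or after subtracting the median of bins of value with GC content or with promoter class, 20 bins each.

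The steps were tested on simulated data. Each simulated list held 15 genes and was tested alone. Unchanged random lists had an unadjusted p under 0.05 in 4.50% of cases at promoters and 5.50% at distal sites. They lay outside the central 95% of the ratio in 6.50%. Lists set fully open had an unadjusted p under 0.05 in 100% of cases and lists with 3 sites added per gene in 87.0%. Lists shifted by 0.25 log2 lay outside in 79.0%. Adjustment over all lists and other list sizes were not simulated, so these shares do not give the power of the adjusted tests. The search found 100% of planted motif matches and none in control windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Raw reads and allele-specific signal were not analysed here, so hybrid alleles were not told apart. No paired analysis was possible because the samples form 1 group.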

Results

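DNase-seq, which marks DNA open to cutting by DNase I, was carried out on lung tissue of adult male B6CASTF1/J mice, F1 hybrids of a B6 and a CAST parent, aged 18 to 20 months. The labels place both samples in 1 group as biological replicates 1 and 2, and give no treatment or other contrast. The questions the design allows are therefore which sites were accessible in lung, near which genes they lay, and how closely the replicates repeated each other. The labels give separate biosamples but the same donor entry, and nothing in them says that the tissue came from separate animals. Every spread and p-value given here measures only these 2 libraries, or genes, peaks and footprints within them, and no test between animals was possible. Replicate 1 had 129336 peaks over 25.3 Mb, 0.954% of the ungapped genome, and replicate 2 had 144880 peaks over 28.7 Mb, 1.08% of it. Read as counts of cuts, the median peak held 135 in replicate 1 and 104 in replicate 2. The median peak value was 0.743 and 0.664 on the authors' scale. The scale is not stated, so the total depth of each library is unknown. Intervals given for shares and counts cover counting error only.

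Most accessible sites of the lung were found in both replicates, and nearly all strong sites were. A peak of replicate 2 overlapped 77.9% of replicate 1 peaks (95% Wilson interval 77.6 to 78.1), and a peak of replicate 1 overlapped 69.6% of replicate 2 peaks (69.4 to 69.8). Random placement within chromosomes gave means of 2.34% and 2.04%. The shared part came to 50.9% of all bases covered by either list, against 0.561% by random placement. Sharing rose with peak value, from 30.1% in the lowest decile of replicate 1 to 99.9% in the highest, and from 19.9% to 99.1% in replicate 2. Shared peaks had median values of 0.952 and 0.926 in replicates 1 and 2, and unshared peaks 0.385 and 0.351.

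**Figure D1:**
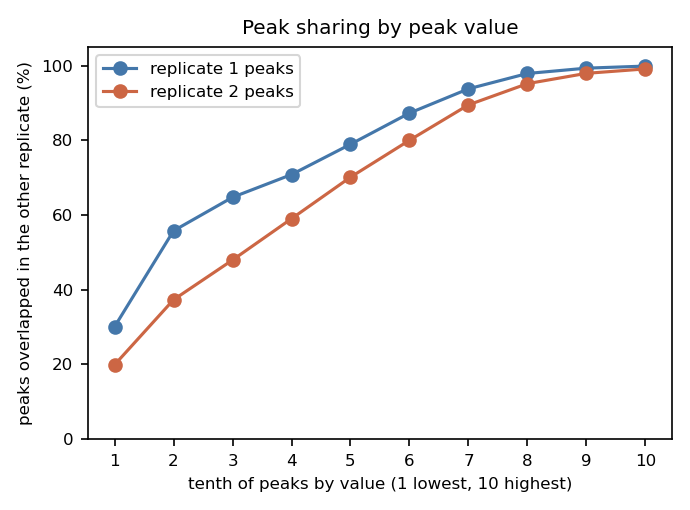
Percent of each replicate's peaks overlapped by a peak of the other replicate (y axis), by decile of peak value (x axis, 1 lowest). Sharing ran from 30.1% to 99.9% for replicate 1 and from 19.9% to 99.1% for replicate 2.

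Across 99200 pairs of shared peaks the values of the replicates had a Spearman correlation of 0.905 and a Pearson correlation of log2 values of 0.940, across peaks, which are not independent replicates. The median log2 ratio of replicate 2 to replicate 1 was -0.16, and 94.9% of the pairs lay within 2-fold of it. The SD of the log2 ratio was 0.50, larger than the 0.18 that counting of cuts alone would give if 1 step of the scale is 1 cut. After Benjamini-Hochberg adjustment of a 2-sided exact binomial test per pair, 44142 pairs (44.5%) differed from the median ratio by more than counting error. The ratio depended on strength, with a median of -0.02 in decile 3 of the mean value and -0.39 in the highest decile. The test used 1 median ratio for all pairs, and each value was taken over that replicate's own peak boundaries. How much of the excess came from the trend with strength or from unlike boundaries was not tested.

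All 10 of the strongest shared sites lay within 1000 bp of an annotated transcription start site. Whether reads of multi-copy sequence added to any of them was not tested. In mm10 (GRCm38) coordinates, the highest mean value was at the Dynlt1b promoter (chromosome 17, 6429981 to 6430180), a gene of a dynein light chain, at 58.0 ± 18.9 (SD, n = 2). Next came the promoter of Dnpep, which encodes an aspartyl aminopeptidase (chromosome 1, 75317561 to 75317940), at 44.8 ± 9.93 (SD, n = 2), and that of Gm21887 near the distal end of X (170009841 to 170010160), at 38.6 ± 21.1 (SD, n = 2). The promoters of Hjurp, a chaperone of the centromeric histone, and of Mplkip followed at 37.4 and 36.4. Gm42418, a lincRNA gene, had 35.1, Ankhd1 35.0, Gatad2a 34.3, Esrra, an orphan nuclear receptor of mitochondrial energy genes, 34.0, and Gpbp1 32.8. Each of the 10 had the higher value in replicate 1. The values were not scaled between the libraries, so the SDs include the overall difference between them.

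Accessible sites gathered at promoters. Of the shared peaks, 31.6% lay within 1000 bp of an annotated transcription start site, 4.96 times the 6.38% given by random placement. Exons outside promoters held 4.55% against 3.41% by random placement, introns 35.8% against 40.3%, and intergenic space 28.0% against 49.9%. Promoter peaks were also stronger, with median values of 1.82 and 1.58 in replicates 1 and 2, while intronic peaks had 0.809 and 0.817 and intergenic peaks 0.776 and 0.772. After centring on all shared peaks, the median log2 ratio of replicate 2 to replicate 1 was -0.12 at promoters, 0.09 in introns and 0.06 in intergenic space.

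Genes of the alveolus, the vessels and the lung's own developmental regulators had open promoters in both replicates. All 12 alveolar type 2 genes, all 12 alveolar type 1 genes, 19 of 20 endothelial genes, all 14 lung epithelial transcription factors and all 11 lung mesenchymal transcription factors carried a shared peak within 1000 bp of a start site. Among all 21938 protein-coding genes the share was 66.8%. By 2-sided Fisher's exact test, adjusted over 33 lists by Benjamini-Hochberg, the adjusted p was 0.0283 for each alveolar list, 0.0272 for endothelial genes and for the epithelial factors, and 0.0396 for the mesenchymal factors. The 18 housekeeping genes (adjusted p = 0.0125) and the 15 circadian clock genes (adjusted p = 0.0193) were all open as well, by the same exact test. Genes are the units of these tests and are not independent replicates.

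Among alveolar type 2 genes, which serve surfactant production, the highest promoter values were at Etv5, a transcription factor of the type 2 state (chromosome 16, 22381309 to 22439719), at 23.5 ± 5.96 (SD, n = 2), and at Abca3, the lipid pump of lamellar bodies, at 13.8 ± 3.79. Sftpb, a surfactant protein, had 8.29 ± 0.971 and the mucin Muc1 7.92 ± 1.73. Among alveolar type 1 genes, of the flat cells of gas exchange, Vegfa (chromosome 17, 46016993 to 46032369) had 20.5 ± 0.723, the homeodomain factor Hopx 11 ± 2.34, the water channel Aqp5 7.00 ± 0.931 and Clic5 4.67 ± 0.163. Endothelial promoters were led by Egfl7, a protein secreted by vessel cells (chromosome 2, 26580014 to 26593120), at 11.3 ± 3.77, with the bone morphogenetic protein receptor Bmpr2 at 9.98 ± 0.802, the co-receptor Eng at 8.26 ± 1.28 and the tight junction gene Cldn5 at 8.0 ± 1.51. Emcn, a surface sialomucin of capillaries and veins, had no promoter peak in either replicate. Of the epithelial factors, Foxp1 had 26.8 ± 6.33, Id2 18.9 ± 5.32, Klf5 13.3 ± 4.28 and Cebpa 11.4 ± 3.99. Of the mesenchymal factors, Gli1, a target of hedgehog signalling, had 11 ± 0.639, Tbx3 10.1 ± 1.59, Foxf1 6.33 ± 0.546 and Tbx2 5.05 ± 0.202. The clock genes had the highest summed promoter values of any list, with Per1 (chromosome 11, 69095217 to 69109960) at 65.7 ± 9.66, Tef at 54.4 ± 10.6, Dbp at 45.0 ± 8.91 and Nr1d2 at 41.0 ± 6.07. For comparison, the housekeeping genes Ywhaz, Polr2a, Actb and Gapdh had 39.9, 34.3, 29.6 and 26.6. These values were not scaled between the libraries, and the median log2 ratio of replicate 2 to replicate 1 was -0.33 at promoters. A small SD therefore does not mark a gene that repeated well. After centring on all genes, the promoter ratio was 0.03 for Per1 and 0.26 for Vegfa.

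Promoters of several cell types foreign to lung, and of posterior Hox, erythroid and mast cell genes, were closed more often than those of other genes. Of the spermatogenic genes 1 of 12 was open in both replicates (adjusted p = 0.00147, Fisher's exact test), of the hepatocyte genes 2 of 13 (0.00334), and of the kidney genes 1 of 9 (0.0102). The erythroid genes had 2 of 10 and the posterior Hox genes, which pattern the hind end of the body, 3 of 12 (0.0193 each). Skeletal muscle had 3 of 11 (0.0282), and photoreceptor genes 2 of 8 and mast cell and basophil genes 3 of 10 (0.0396 each, all by Fisher's exact test). Closed promoters included Prm1, a sperm protamine, Ahsg and Apoa1 of the liver, Nphs1 of the podocyte, Alas2 and Gata1 of red cell precursors, Hoxa13, Acta1 of muscle, the photoreceptor factor Crx, and Cpa3 of mast cells. Members that were open in these lists included Dazl (5.68 ± 0.617, SD, n = 2), Apoh (7.41 ± 0.664), Slc12a3 (6.81 ± 1.14), Mylpf (17.3 ± 7.45), Gnat1 (4.96 ± 0.0867) and Gata2, a factor that endothelial cells also use (10.7 ± 1.23). Whether the peaks in these windows belong to neighbouring genes was not tested.

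Immune and blood cell genes were open less often than other genes or did not pass the test. Of the monocyte, interstitial macrophage and dendritic genes 5 of 15 were open (adjusted p = 0.0283, Fisher's exact test), while Ccr2 and Cd209a had no promoter peak. Of the T and NK cell genes 7 of 19 were open (adjusted p = 0.0283, Fisher's exact test), led by the kinase Lck at 9.07 ± 0.166 (SD over both replicates), while Cd3g and Cd4 had none. Counts that did not pass the test were 6 of 11 for alveolar macrophage genes (Pparg 5.12, Chil3 closed), 6 of 12 for neutrophil genes (Mmp9 1.39, Csf3r closed), 7 of 12 for B and plasma cell genes (Ebf1 4.68, Jchain closed) and 4 of 8 for megakaryocyte genes (Itga2b 19.1, Gp9 closed).

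The other lists did not pass the same test, which in lists this small does not show that they were like the rest of the genes. Among airway cells these were ciliated genes with 10 of 12 open (Tppp3 16.6 and the ciliogenesis factor Foxj1 9.75), club and secretory genes with 8 of 11 (Cbr2 6.56, Bpifa1 closed) and basal genes with 5 of 10 (Snai2 4.58, Krt14 closed). Among supporting cells they were smooth muscle and pericyte genes with 12 of 14 (Myh11 2.80), fibroblast genes with 11 of 16 (Pdgfra 10.3, Col1a1 7.61, Lum closed), mesothelial genes with 4 of 8 (Wt1 1.33, Gpm6a closed) and lymphatic endothelial genes with 3 of 5 (Flt4 1.95, Mmrn1 closed). Cardiomyocyte genes had 6 of 14 open (Myl4 15.4, Myh6 closed), adipocyte genes 3 of 8 (Lipe 25.2, Adipoq closed) and neuron genes 6 of 13 (Camk2a 1.92, Neurod1 closed). Anterior Hox genes had 10 of 16 (Hoxa5, a gene of lung development, 4.6), and the senescence and inflammation genes 13 of 18 (Trp53 26.2, Cdkn1a 17.5, Il1a closed).

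In replicate 1 alone the alveolar and mesenchymal factor lists kept all members open but had adjusted p = 0.0590 each (Fisher's exact test), and the myeloid list had 60.0% open (adjusted p = 0.513), the muscle list 36.4% (0.0924), the photoreceptor list 37.5% (0.114) and the posterior Hox list 41.7% (0.107). The T and NK cell list passed in neither replicate alone, the window of 2500 bp ended the spermatogenic (41.7%, 0.124), kidney (33.3%, 0.0705), muscle, photoreceptor, mast cell, alveolar and mesenchymal factor calls, and among sites above the median value the mesenchymal factors stood at 63.6% (adjusted p = 1), with the mast cell (0.156) and photoreceptor (0.113) calls lost by the same exact test.

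**Figure D2:**
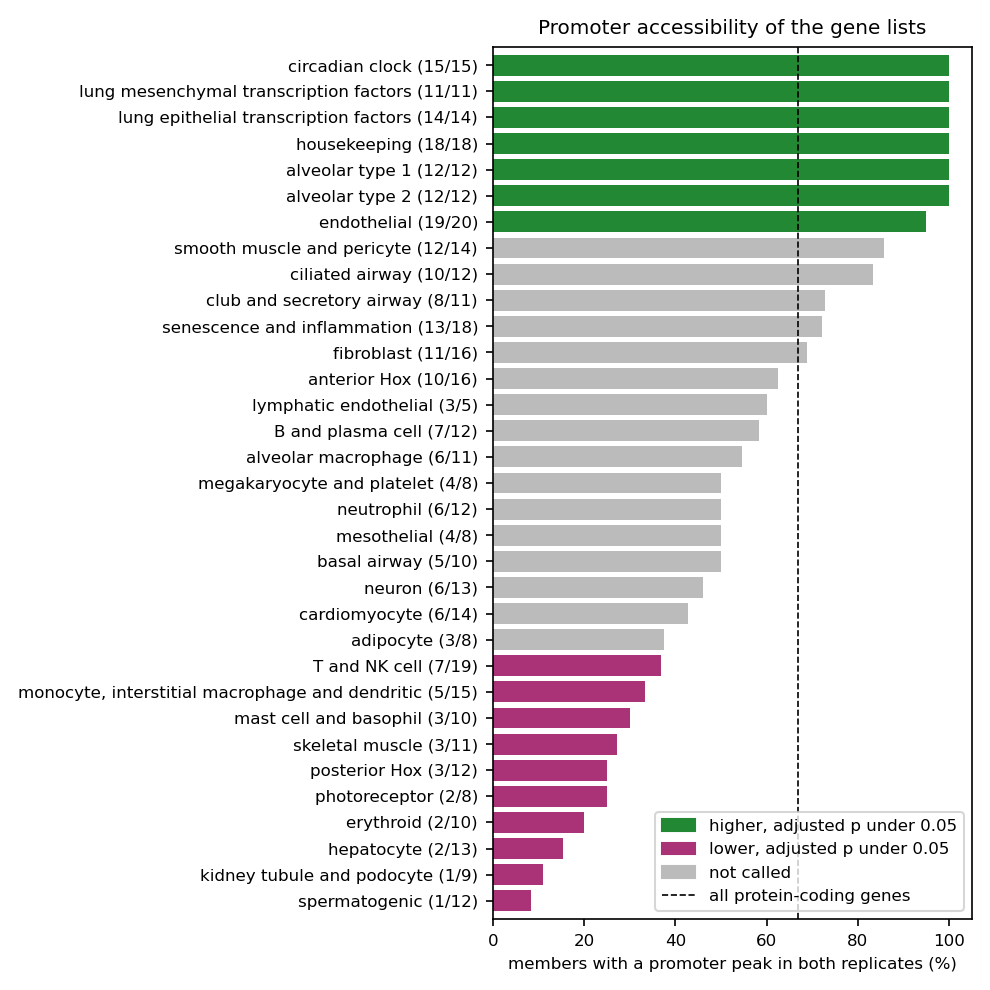
Percent of each list's genes with a promoter peak in both replicates (bars, open and measured genes in brackets), with the share among all protein-coding genes, 66.8%, as a dashed line. Of 33 lists, 7 were called higher and 10 lower by Fisher's exact test at an adjusted p under 0.05.

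Away from promoters, the clock genes were the only list with a surplus of accessible sites past the threshold. They had a mean of 5.40 shared distal sites within 10000 bp of the gene body, against a median of 2.33 in random lists matched on gene length (2-sided permutation p = 0.00140, adjusted p = 0.0462). There were 9 sites at Per1 and 7 at Tef, but 1 at Nr1d2 and 0 at Dbp. Lung epithelial transcription factors had 6.71 sites against 2.86 (adjusted permutation p = 0.168), with 38 at Foxp1, endothelial genes 5.95 against 3.20 (0.165), with 9 at Egfl7, and alveolar type 1 genes 4.83 against 2.58 (0.195), with 9 at Clic5. Mesothelial genes had 0.75 against 3.0 (adjusted permutation p = 0.165). With 50000 bp on each side the alveolar type 1 (mean 11.8, adjusted permutation p = 0.0264) and endothelial lists (11.1, 0.0478) passed as higher and the mesothelial list as lower (2.00, 0.0374). The clock call was lost in replicate 1 alone (6.27, adjusted permutation p = 0.154) and among sites above the median value (3.53, 0.0594), and anterior Hox genes passed in replicate 1 alone (5.56 against 2.25 shared sites, 0.0396).

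Endothelial genes had higher values in replicate 2, throughout the list. Their summed peak value over the gene body and 10000 bp on each side had a median log2 ratio of 0.58 relative to all protein-coding genes, and 20 of 20 genes lay above 0. Egfl7 stood at 0.98, Cldn5 at 0.90, Bmpr2 at 0.59 and Eng at 0.54. In random lists matched on value the central 95% ran from -0.13 to 0.14, and the endothelial median lay at percentile 100. Summed over its genes, the list had 185 peaks over 39.6 kb in replicate 1 and 233 peaks over 50.5 kb in replicate 2, with mean values of 1.48 and 1.47. Over shared peaks alone, a comparison added after the data were seen, the ratio was 0.52 (percentile 100). These are comparisons of 2 libraries and carry no p-value.

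Mesothelial genes and lung epithelial transcription factors were lower in replicate 2. The mesothelial median was -0.69 (1 of 6 measured genes above 0), with Msln, the mesothelin gene (chromosome 17, 25748613 to 25754378), at -2.81 and Wt1, a factor of the mesothelium, at -1.84. At their promoters alone Msln stood at -1.35 and Wt1 at -1.62. The Msln sum was 3.43 in replicate 1 and 0.409 in replicate 2, where only its promoter added to the sum. Summed over its genes, the list had 23 peaks over 4.97 kb with a mean of 0.788 in replicate 1, and 19 over 3.13 kb with a mean of 0.468 in replicate 2. Over shared peaks alone it was -0.41 (percentile 1.02). The epithelial factors stood at -0.21 (2 of 14 above 0), with Cebpa at -0.40, Klf5 at -0.22, Id2 at -0.12 and Foxp1 at 0.15. Summed over genes, their peaks went from 233 over 53.1 kb (mean 1.49) to 202 over 43.6 kb (mean 1.28). As the median over each gene's shared peaks, a measure added after the data were seen, the epithelial factors were at -0.23 (percentile 0.73), and after correction for GC content and value at -0.15 (percentile 3.74), inside the random range. After correction for value and promoter class they were at -0.19 (percentile 1.72), outside it.

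The other 4 of the 7 lists outside the random range moved in both directions. Alveolar type 1 genes stood at 0.17 (10 of 12 above 0, Clic5 at 0.69 and Hopx at 0.57) and fibroblast genes at 0.29 (11 of 16, Limch1 at 0.64). At the promoters of these genes Clic5 stood at 0.40 and Limch1 at 0.25, but Hopx at -0.10, in the other direction. At promoters alone both lists lay inside the range, at 0.19 and 0.25. With values summed over shared peaks alone they were at 0.17 (percentile 98.97) and 0.24 (98.6), outside it, but as the median over each gene's shared peaks at -0.01 (5 of 12 above 0, percentile 66.05) and 0.05 (10 of 15, 81.9), inside it. Spermatogenic genes stood at 0.40 (8 of 9 measured) and B and plasma cell genes at -0.31 (4 of 11 above 0, Cd79b at -1.34, and -0.70 at its promoter). With 1 of 12 spermatogenic promoters open and a mean of 0.75 distal sites per gene, the spermatogenic ratio may largely describe neighbouring genes. The erythroid gene Klf1 shows such a window, with 0.567 and 0 at its promoter in replicates 1 and 2 but 45.8 and 31.7 over the window. Over shared peaks alone the spermatogenic ratio was 0.11 (percentile 85.3) and the B and plasma cell ratio 0.01 (percentile 48.3), both inside the random range. As the median over each gene's shared peaks they were at -0.04 (4 of 9 above 0, percentile 72.3) and -0.11 (1 of 11, 24.7), inside it too. At promoters alone the B and plasma cell genes stood at -0.57 (1 of 7 above 0, percentile 0.56), outside the range. In all 6 lists lay outside at promoters. The others were endothelial genes (0.63), mast cell and basophil genes (0.76, 3 of 3 above 0), ciliated genes (0.24, 6 of 10), mesothelial genes (-1.15) and the epithelial factors (-0.23). Anterior Hox genes stood at -0.05 over all peaks. Over shared peaks alone they stood at 0.41 (percentile 100), and as the median over each gene's shared peaks at 0.20 (11 of 15 above 0, percentile 99.7). At promoters alone they stood at -0.14 (5 of 11, percentile 15.9). Hox genes lie in clusters and share windows, unlike the genes of random lists. Summed over these genes, their windows held 199 peaks over 51.1 kb in replicate 1 and 95 over 19.5 kb in replicate 2. A peak in several windows was counted once per gene, so these are not numbers of distinct peaks.

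The median of all protein-coding genes, to which these ratios are relative, was itself -0.26, and scaling each library to its total peak value moved it to -0.07. In simulated lists with no change 6.50% lay outside the central 95%, and the labels offer no group to which the differences could be tied.

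**Figure D3:**
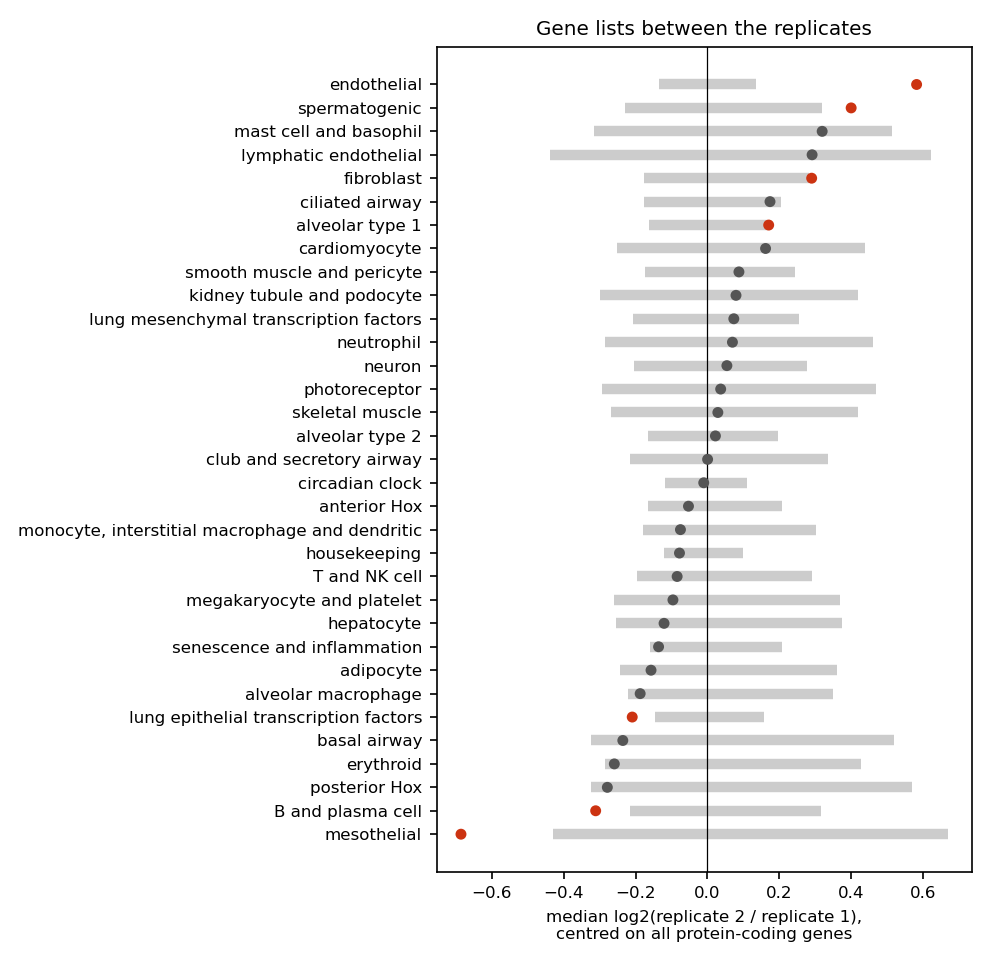
Median log2 ratio of replicate 2 to replicate 1 of the summed peak value per gene list, relative to all protein-coding genes (points; red, outside the grey bar). Grey bars show the central 95% of random lists matched on value, and the endothelial list stood at 0.58 with 7 of 33 lists outside.

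Sites with the largest ratios between the replicates included 2 at the repeat-masked start of chromosome 9. Among shared peaks above the median value, the largest ratio was at an intergenic site 35530 bp from Pak3, a kinase gene on X (143482981 to 143483140). This site had 2.78 in replicate 1 and 39.4 in replicate 2, or 506 and 6175 cuts if 1 step of the scale is 1 cut. It was followed by sites near Slc12a2 (0.341 and 2.63), in Gm10718 (0.253 and 1.90), in Ube2e2 (0.424 and 2.93) and in Gm11168 (2.15 and 14.2). The sites in Gm10718 and Gm11168 are those on chromosome 9, and 97.3% and 100% of their bases are soft-masked as repeats. The largest ratios toward replicate 1 were near 4930556I23Rik (1.94 and 0.421), in an exon of Gm21887 (3.13 and 0.798), near Gm17944 (1.72 and 0.485), near Cyth4 (2.01 and 0.575) and near Gm33142 (1.88 and 0.543).

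The X chromosome had fewer and weaker sites than any autosome in both replicates. It carried 19.5 and 23.1 peaks per Mb in replicates 1 and 2, against autosomal medians of 54.7 and 59.8, or 0.357 and 0.386 of them. The lowest autosomes had 39.3 and 46.0 peaks per Mb, and chromosome 11 was highest with 80.3 and 86.7. The median value of an X peak was 0.429 and 0.364, or 0.574 and 0.548 of the autosomal medians. Promoter peaks on X had 0.622 and 0.618 of the autosomal median value and other peaks 0.547 and 0.522. Among peaks above the median value of all chromosomes, X had 0.220 and 0.208 of the autosomal density. The labels give male animals, which carry a single X. The Y chromosome had 109 and 84 peaks, or 1.24 and 0.953 per Mb, with median values of 0.154 and 0.121.

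**Figure D4:**
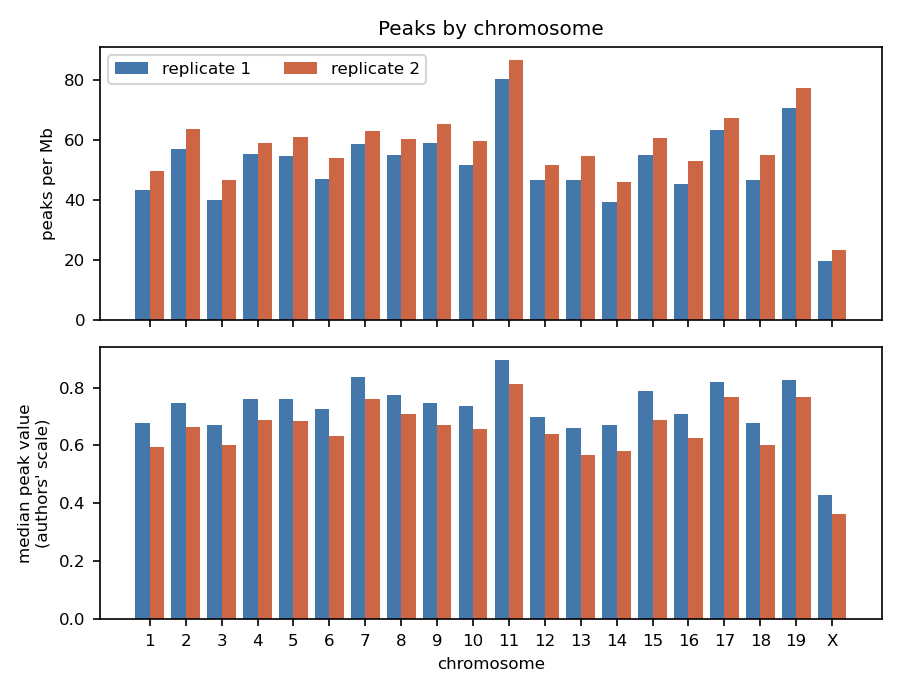
Peaks per Mb (upper panel) and median peak value on the authors' scale (lower panel) for chromosomes 1 to 19 and X in each replicate. Of these chromosomes X was lowest on both measures, with 19.5 and 23.1 peaks per Mb.

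Footprints, short stretches protected from cutting inside open sites, were listed in similar numbers. Replicate 1 had 375253 and replicate 2 had 365321, with a median width of 10 bp in both. Of these, 83.7% and 86.1% lay inside peaks, and 84.6% and 78.3% of peaks held at least 1. That share rose with peak value, from 38.3% and 20.6% in the lowest decile to nearly all peaks in the highest. A footprint of the other replicate overlapped 51.0% of replicate 1 footprints and 53.6% of replicate 2 footprints, against 19.2% and 25.2% for random placement inside peaks. Only replicate 2 footprints inside peaks were placed at random, while the observed shares use all footprints. The placement spread them evenly over peak bases and did not keep their gathering in strong peaks. The random shares may therefore be too low.

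The motif most enriched in footprints was that of CTCF among those with more than 9 window matches, and of motifs of lung regulators some were enriched and others depleted. Each footprint, with 5 bp on each side, was compared with a window of the same width displaced inside the same peak. Of 24 sequence motifs, 13 were more frequent in footprints in both replicates and 4 were less frequent in both (2-sided Fisher's exact test on footprints, which are not independent replicates, Benjamini-Hochberg over motifs). CTCF, the insulator protein, was matched in 1.38% of footprints and 0.0169% of windows in replicate 1, a log2 ratio of 6.36, and of 6.28 in replicate 2. NRF1 stood at 5.02 and 4.81, CREB at 4.27 and 4.54, and SP/KLF at 4.01 and 3.95. The adjusted p was 1e-300, the smallest value reported, for CTCF and SP/KLF, and at most 1.41e-188 for the other 2. NKX2-1, the master regulator of lung epithelium, was at 0.87 and 1.0 (adjusted p 1.57e-32 and 1.0e-45), and CEBP, a family active in alveolar type 2 cells, at 1.04 and 1.12. The CACGTG E-box was at 1.27 and 1.23, E2F at 1.66 and 1.53, YY1 at 0.96 and 0.91, and AP-1 at 0.38 and 0.44. Motifs with few window matches are given as ratios of counts with exact 95% intervals. RFX had 109 footprint matches against 6 window matches in replicate 1, an 18.2-fold ratio (interval 8.08 to 50.6), and 100 against 9 in replicate 2, 11.1-fold (5.62 to 25.01). NFI had 99 against 5 in replicate 1, 19.8-fold (8.21 to 62.3), and 141 against 1 in replicate 2, 141-fold (24.9 to 5608). REST, a repressor of neuronal genes, had 35 against 1 in replicate 1, a 35.0-fold ratio (interval 5.88 to 1421), and in replicate 2 it had 18 against 0, 6-fold against a floor of 3 counts, with 4.40 as the lower limit of the exact 95% interval.

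FOXA motifs were less frequent in footprints than in displaced windows, at -1.67 and -1.18, as were GATA (-0.96 and -0.43), ETS (-0.40 and -0.52) and the glucocorticoid receptor motif GR (-1.52 and -1.46). IRF went opposite ways, at -0.23 in replicate 1 and 0.30 in replicate 2. RUNX passed in replicate 1 alone (0.21 against 0.08, adjusted p = 0.0159 and 0.375, Fisher's exact test), and the difference between the replicates was not tested. NFY, TEAD, SRF, MEF2 and SOX passed in neither replicate. Footprint windows were richer in G and C than displaced windows, at 58.9% against 54.2% in replicate 1 and 57.3% against 53.4% in replicate 2. With windows matched on this content the GATA call was lost in replicate 2 (-0.04) and the YY1 call in replicate 1 (0.50), and TEAD, RUNX, IRF and SOX passed as higher in both replicates. The values of SP/KLF fell to 3.16 and 3.13 and those of NRF1 to 4.38 and 4.27, while CEBP rose to 1.55 in both and FOXA stood at -1.17 and -0.78. Without the 5 bp extension AP-1, YY1 and GR no longer passed in both replicates, and NFY, TEAD and RUNX passed as lower.

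**Figure D5:**
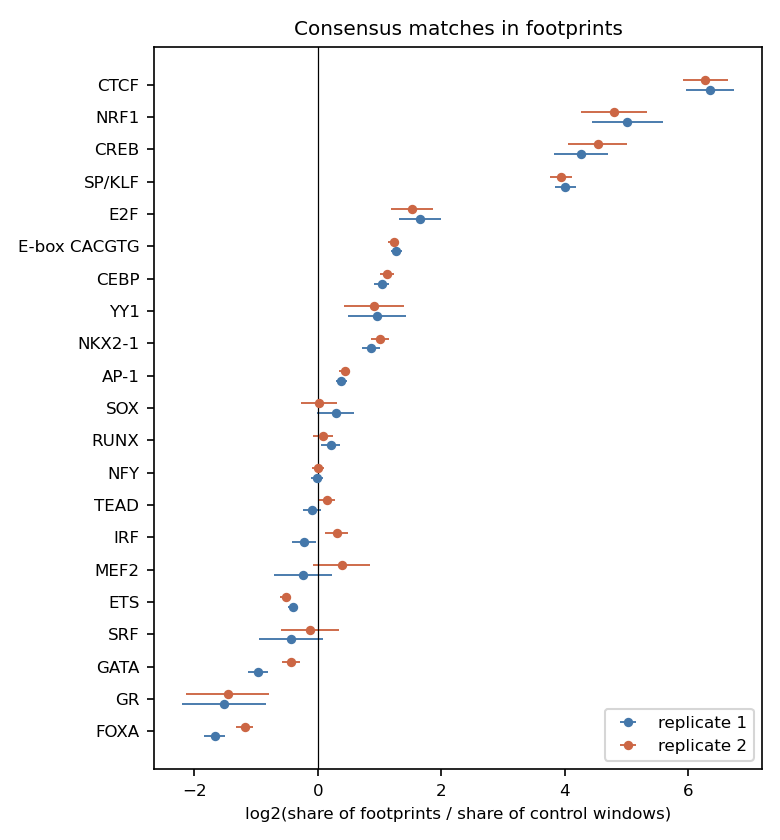
Log2 ratio of the share of footprints with a motif match to the share of displaced control windows with one (x axis), per motif and replicate, with 95% counting intervals. Among the motifs drawn, CTCF stood highest at 6.36 and 6.28, FOXA lowest in replicate 1 at -1.67 and GR lowest in replicate 2 at -1.46. NFI, RFX and REST, with 9 or fewer window matches, are left out.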

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

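All alternatives were chosen before the data were examined except 3, which were added afterwards: both settings without mostly repeat-masked peaks, and the ratio over shared peaks only. Peaks of the lowest value decile were shared least, but the total depth of each library is unknown and what depth limits was not tested. The spread of 2 libraries limits every comparison between them. Of the main values and counts 38 stayed within their spread, or within 1.5 times for a count, and 36 moved. Of the other results 494 kept their side of the threshold, and their direction where they passed. Results that passed in neither setting are among these even where their direction turned. A further 26 passed only under the alternative, 32 no longer passed and 10 turned direction with a call in either setting. The causes were not tested unless the setting itself gives them. No paired analysis was possible because the samples form 1 group.

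With the shorter list, replicates 1 and 2 had 83534 and 91246 peaks by construction, and X had 0.333 and 0.355 of the autosomal peaks per Mb and 0.665 and 0.605 of the median value. Above the median value, there were 64803 and 72506 peaks, again by construction. There the Spearman correlation was 0.865 and Pearson's 0.929, promoters held 43.3% of shared peaks, X had 0.220 and 0.208 of the autosomal peaks per Mb with 1.09 and 0.998 of the median value, a measure that the common cutoff itself brings closer, and 0 lists passed as higher at distal sites.

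With 50% reciprocal overlap, 66.8% of replicate 1 and 59.7% of replicate 2 peaks were shared, the correlations were 0.914 and 0.945, and 37.3% and 38.4% of footprints were shared, fewer because the requirement is stricter. With equal numbers of top peaks, set at 50% of the replicate 1 count for each list, 83.7% of replicate 2 peaks and 60.4% of bases were shared. This setting also leaves out weak peaks, which were shared least, and the part due to equal numbers was not tested. Inside shared peaks only, 57.1% and 61.4% of footprints were.

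The promoter share of peaks was 27.9% to 29.6% in either replicate alone, 24.7% with 500 bp, 41.8% with 2500 bp and 27.7% with protein-coding genes only. Lists passing as lower at promoters numbered from 5 to 9 in either replicate alone. With 2500 bp, 4 passed as higher and 5 as lower. At distal sites with 50000 bp, 3 passed as higher and 1 as lower.

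Over shared peaks only, the B and plasma cell ratio of summed values turned to 0.011, while at promoters alone it was -0.57 and as the median over each gene's shared peaks -0.11, and that of anterior Hox genes to 0.41. Without the motif extension, log2 ratios turned for NFY (-0.24) and TEAD (-0.67) in replicate 2, for RUNX in both (-0.51 and -0.78), for IRF in replicate 2 (-0.17) and for SOX in replicate 1 (-0.66). With GC-matched windows those of TEAD (0.30) and IRF (0.24) turned in replicate 1.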

Other observations

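The tests in this part were chosen after the replicate ratios of the lists, the site ratios and the X chromosome values had been seen. For the endothelial tests, what each explanation required was written down before the test was run.

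Distal sites higher in replicate 2 and distal sites higher in replicate 1 held different motifs. Of 27733 autosomal non-promoter shared sites above the median value and at most 80% repeat-masked, the 2773 with the highest and the 2773 with the lowest ratio of replicate 2 to replicate 1 were compared over 200 bp around the midpoint. A match does not tell which factor of a family was bound, or in which cell type. With the ratio corrected for GC content and value, ETS motifs were in 16.7% of the sites higher in replicate 2 and in 6.67% of those higher in replicate 1 (log2 ratio 1.32, adjusted p = 2.72e-30, 2-sided Fisher's exact test over 24 motifs). SOX motifs were in 52 against 8 sites (adjusted p = 2.10e-08, Fisher's exact test), GATA in 7.07% against 3.03% (3.22e-11) and FOXA in 8.94% against 3.86% (5.92e-14). CTCF was in 7.18% against 4.44%, and in 9.21% of all these sites; with the correction for value and promoter class alone it was in 7.68% against 2.74%. Sites higher in replicate 1 held more AP-1 (12.9% against 6.38%, adjusted p = 1.77e-15, Fisher's exact test), CEBP (8.08% against 4.47%, and 7.00% against 5.45% with the correction for value and promoter class alone), CACGTG E-box (6.78% against 3.61%) and RUNX motifs (4.47% against 2.16%). NKX2-1 did not pass (3.14% against 2.27%, adjusted p = 0.104, Fisher's exact test). In all 11 motifs passed, and 13 did with the correction for value and promoter class alone, where mean GC content was 49.4% in sites higher in replicate 2 and 54.3% in the others. Sites are the units and are not independent replicates.

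Endothelial genes, with 19 of 20 promoters open in lung as a whole, had higher values in replicate 2, at a median log2 ratio of 0.38 over shared peaks (19 of 20 above 0) and with promoter values of 8.61 and 13.9 at Egfl7 in replicates 1 and 2. The ratio fell with GC content across peaks (Spearman -0.336), but the list stood at 0.40 (20 of 20, percentile 100 of random lists) after correction for GC content and value, so GC bias was not the whole cause. It stood at 0.37 (19 of 20) after correction for signal strength and promoter class, which argues against signal strength in the same way. The rise was not limited to this list. After correction for GC content and value, anterior Hox genes stood at 0.27 (percentile 100) and mast cell and basophil genes at 0.27 (99.49). Photoreceptor genes were at 0.20 (97.65) and lung mesenchymal transcription factors at 0.17 (98.18), all above the random range. A larger share of endothelial nuclei in replicate 2 remains a candidate explanation, as a hypothesis. It required a list of 27 other endothelial genes to lie above the random range, and these stood at 0.40 (22 of 27, percentile 100); whether dissection, nuclei isolation or the animals themselves gave such a difference was not tested, and the design gives no biological group.

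The lung epithelial transcription factors, lower in replicate 2, stood at -0.23 over shared peaks before correction (random range -0.19 to 0.13). After correction for GC content and value they stood at -0.15 (-0.17 to 0.12). This call ended there because the median moved toward 0, to just inside the range. In both settings 0 of 14 factors lay above 0. After correction for value and promoter class they stood at -0.19 (-0.17 to 0.13, 0 of 14 above 0), still outside. The mesothelial list stood at -0.60 before (-0.40 to 0.30) and -0.59 after (-0.45 to 0.22), and at -0.61 (-0.46 to 0.23) after the second correction. The other lists chosen for the same purpose, given as values after correction for GC content and value, stood at -0.10 for 20 epithelial genes (percentile 4.01, inside the range, and -0.18 at 1.48 without correction), -0.18 for 17 B cell genes (1.72, and -0.29 at percentile 0.11 without correction), -0.31 for 8 mesothelial genes (0.34, and -0.26 at 1.61 without) and -0.02 for 16 fibroblast genes (62.5, and -0.06 at 44.7 without). After correction for value and promoter class they stood at -0.12 (percentile 2.67), -0.16 (3.73), -0.27 (1.73) and -0.12 (20.1), so the epithelial and B cell lists lay inside the range and the mesothelial list outside.

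The largest ratios included satellite-like sites. If reads from many repeat copies pile up on the few copies in the reference, sites over 2-fold higher in replicate 2 might be rich in mostly repeat-masked peaks. With the 10 sites that the report names for their ratio left out, since they prompted the test, 7 of 1368 such sites (0.512%) were mostly masked against 102 of 48223 others (0.212%), an odds ratio of 2.43 with a 95% interval of 0.950 to 5.196, which includes 1 (p = 0.0316, 2-sided Fisher's exact test). In sites over 2-fold higher in replicate 1 the ratio was 3.004 (0.358 to 11.2, 2 of 308). Too few masked sites were found to decide, so the explanation stays open, and no biological explanation was tested by the design.

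X-linked sites had lower values than autosomal ones. Fewer annotated promoters on X, and so a lower share of strong promoter peaks, would leave values within promoter peaks and within other peaks in the range of the autosomes. The median X value lay below every autosome in both classes and both replicates, at 0.622 and 0.618 of the autosomal median for promoter peaks and 0.547 and 0.522 for other peaks, which argues against this as the whole cause. The upper quartile of promoter values on X was 0.566 of the autosomal median in replicate 1 and 0.560 in replicate 2, and the median value 0.508 and 0.509. Of its coding genes 47.9% had an open promoter against 55.7% to 78.5% on the autosomes, and it had 0.180 shared promoter peaks per start site against 0.197 to 0.309, which weaker peaks under the calling threshold or lower activity of X-linked genes would both give. A single copy of X in male animals stays open as an explanation, because these low ratios were foreseeable from the peak values and no test here could set it apart from lower mappability, which was not tested, or from lower activity of X-linked genes.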
